A study of Caenorhabditis elegans with 2 samples.

How the data were processed

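The series is a chromatin immunoprecipitation sequencing (ChIP-seq) experiment on whole L3 larvae of Caenorhabditis elegans of mixed sex. The strain, OP234, carries the integrated transgene wgIs234, which expresses JUN-1 fused to eGFP, in an unc-119(ed3) background. JUN-1 is a bZIP transcription factor of the AP-1 class, whose members bind DNA as pairs. The labels name 2 biological replicates of this 1 group, so no comparison between conditions could be made, and controls named in the labels were not analysed here. Each p-value below compares sets of regions or genes within this experiment.

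The authors deposited peak lists in narrowPeak format on builds ce10 and ce11. Per the text files deposited beside the samples, the list of each replicate was derived from that replicate's alignments and a control, a pooled list from both replicates, and an IDR list (irreproducible discovery rate, a measure of how alike replicates rank regions) from the pooled and both replicate lists. Peak caller, aligner, software versions and read depth are not given in the sources used here, so the depth behind each region is unknown. Each region carries the authors' signal value, a score from their peak calling whose scale is not stated, and the authors' −log10 of a q-value, with no p-value given. In the IDR list 2677 of 2738 peaks share the highest −log10 q of 3.73, so ranks were taken from the deposited signal score. Signal values were used only to rank, filter and describe regions within a list. The 2738 IDR peaks on ce11 were the same number as the pooled regions at or above their lowest signal value, 31.4.

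All results use ce11, which has the chromosome lengths and names of the WBcel235 reference. Genes came from Ensembl release 115, with 19973 protein-coding genes on the nuclear chromosomes. The 17626 pooled regions that overlapped no IDR peak served as background of the same assay and are called lower-ranked regions; 456 further pooled regions that overlapped an IDR peak were in neither set. A summit lay in a promoter when it fell from 1000 bp upstream to 500 bp downstream of the 5′ end of any protein-coding transcript, and a gene with such a summit is called bound. Bound describes a listed region near a gene, not an effect on its transcription. Of the 1902 bound genes, 799 shared their strongest peak with another gene. Replicate regions were matched to an IDR peak by the nearest summit within 200 bp.

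Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 14 motifs, the 27 gene lists or the noncoding classes. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error of regions or genes only, and regions were treated as independent. The overlap of the replicates' top-ranked regions was compared with 1000 seeded random placements per chromosome in a one-sided permutation test. Motifs were searched on both strands within 50 bp of the summit. Gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule takes the gene with the nearest 5′ end for the 25 strongest IDR peaks, up to 4 bound members of highest signal value per list (6 where the list passed), and jun-1, fos-1 and unc-119 in any case. List members with no protein-coding gene in the annotation, 9 in all, were left out. Alternatives varied the genome build, matching distance, number of peaks, promoter and motif windows, background and use of each replicate alone. In the last of these, the 2738 strongest regions of a replicate were set against the other regions of its own list. Comparisons with lower-ranked regions of the same GC content, on autosomes only, without the 100 strongest peaks, with matched gene sets and with random draws from the replicate lists were added after seeing the data.

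The statistics were tested on simulated data. With 5 lists planted at 40% bound among 19973 genes, 90.8% of planted lists were called and 0.818% of the others. With 3 motifs written into 2% of windows drawn from 17626 lower-ranked regions, 100% of planted motifs and 0.909% of the others were called. Independent random sets of 2738 regions passed the overlap test in 5% of runs, and sets sharing 5% of summits in 100%. Outside the planted lists, genes were bound independently in these simulations, and motif windows were split at random. Peaks shared by genes and the GC difference between the real sets were not simulated, so the rates do not cover them. Lists of 16 to 19 members were never planted. Nor were the GATA, SKN-1, FOXO, heat shock element, Hox/PBC, TATA and SL1 motifs. The rates of 90.8% and 100% therefore say nothing about how often these would be called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.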

Results

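Binding of eGFP-tagged JUN-1 was mapped by ChIP-seq in whole L3 larvae, with 2 biological replicates of 1 group. The question the design poses is where in the genome the tagged factor is found at this larval stage. The authors' IDR list on ce11 held 2738 peaks, the pooled list 20820 regions, and the replicate lists 27417 (replicate 1) and 28475 (replicate 2). The median width of an IDR peak was 390 bp. IDR peaks had a median signal value of 47.7, a score given by the authors for the pooled replicates, with a range of 31.4 to 474.

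The strongest regions were largely shared by the replicates. Among the 2738 regions of highest signal value in each replicate list, 1830 of replicate 1, or 66.8% (95% interval 65.0 to 68.6%), had a summit within 200 bp of one from replicate 2. Random placement on the same chromosomes gave 1.10% on average and at most 1.83% (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Random draws of as many regions from the complete replicate lists, a comparison added after seeing the data, gave 4.05%. Of the IDR peaks, 2710 (98.98%) lay within 200 bp of a summit in the list of replicate 1 and 2729 (99.7%) in that of replicate 2. The IDR list was derived from these lists, so such presence is largely built in and is no separate support. Among the top-ranked regions of both replicates were 1818 IDR peaks (66.4%).

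Across the 2702 IDR peaks matched in both replicates, log10 signal values had a Pearson r of 0.575, and Spearman's rho was 0.479 (95% bootstrap interval 0.445 to 0.510). Peaks are not independent replicates, so no p is given, and peaks were selected on their pooled value, which narrows the range the correlation is computed over. The median ratio of replicate 2 to replicate 1 was 1.40. Signal values below are therefore given for each replicate beside the pooled one.

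**Figure D1:**
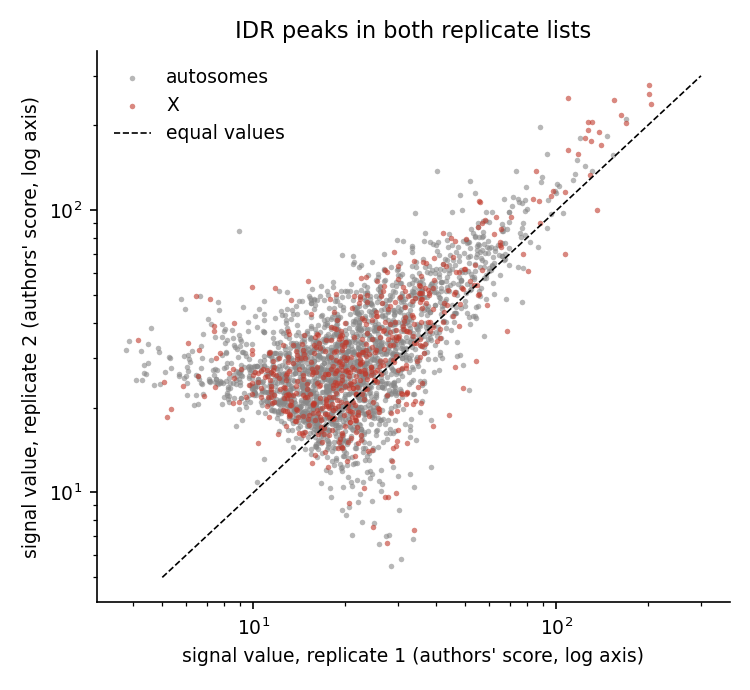
Signal value of replicate 1 (x axis, authors' score, log axis) against replicate 2 (y axis, authors' score, log axis) for the 2702 IDR peaks found in both replicate lists, with X-linked peaks in red, autosomal peaks in grey and equal values as a dashed line. Most points lie above the line, at a median ratio of 1.40, and the points with the highest values in both replicates are mainly on X.

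Most of the 25 strongest peaks lay on X and away from annotated promoters. Of these IDR peaks of highest signal value, 17 were on X and 10 were in a promoter. The 4 strongest were X-linked and outside promoters. The first, at 13700644 to 13701033, was intergenic, with its summit 6065 bp upstream of the nearest 5′ end, that of K02D3.1 (signal value 474 pooled, 202 in replicate 1 and 278 in replicate 2). The second, at 11093932 to 11094395 (456 pooled, 202 and 259), was intergenic near W02H3.3. The third, at 6296346 to 6296815 (444 pooled, 206 and 239), was in an intron of mom-1, and cest-16 had the nearest 5′ end. The fourth, at 9465686 to 9466035 (401 pooled, 155 and 246), was intergenic near ZK899.6. A peak at X 8036209 to 8036668 lay 4880 bp upstream of xol-1, the switch gene of sex determination and dosage compensation (304 pooled, 124 and 181).

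Other X-linked peaks among these 25 that were outside promoters had their nearest 5′ end at F20B6.9, Y41G9A.17, F19H6.5, T27A8.7, F55G7.5, F22H10.2, gtr-1, C41A3.2 and C30E1.4. The peak nearest C41A3.2 was 15192 bp from it, in a coding exon of pks-1, a polyketide synthase gene. The X-linked promoter peaks were those of cebp-1, a C/EBP-type bZIP gene (276 pooled, 118 and 158), ins-39, an insulin-like peptide gene (267 pooled, 109 and 164), and nspc-17 (377 pooled, 164 and 218).

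Of the autosomal peaks among the 25, the strongest lay upstream of the ribosomal protein gene rpl-3, at III 3867438 to 3867717, with its summit in intergenic sequence 283 bp from the 5′ end (378 pooled, 169 and 211). Promoter peaks also marked tasp-1 (328 pooled, 147 and 184), cdc-48.1, which encodes a p97-type AAA ATPase (292 pooled, 88.4 and 198), rpl-15 (268 pooled, 117 and 151) and egg-5 (267 pooled, 132 and 138). A peak at II 5844687 to 5844867 had its nearest 5′ end at ZK1248.17 (266 pooled, 125 and 143). Its summit was 734 bp downstream of that end, outside that gene's window, and it counted as a promoter peak through another gene. A peak at IV 4749926 to 4750197 lay 175 bp upstream of Y17G9B.5 and 287 bp upstream of rpl-20 (303 pooled, 119.4 and 180). The remaining one was in an intron of Y111B2A.12 on chromosome III (311 pooled, 153 and 157).

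Over all IDR peaks, binding was promoter-centred. Promoter windows held 1584 of 2738 summits (57.9%, 95% interval 56.0 to 59.7%) against 41.3% of 17626 lower-ranked summits (odds ratio 1.95, Fisher's exact test, p = 1.09e-58) and 31.2% of random positions. The median distance to a coding 5′ end was 594 bp at IDR peaks and 1036 bp at lower-ranked regions. Coding exons held 2.45% of IDR summits against 13.6% of lower-ranked ones (odds ratio 0.159, adjusted p = 4.80e-83, Fisher's exact test). 3′ UTRs held 2.15% against 5.80%, and introns 23.4% against 33.2%. 5′ UTRs held 4.09% against 2.57%, intergenic sequence 61.6% against 41.9%, and noncoding genes or pseudogenes 6.14% against 2.72%.

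The X chromosome had 574 IDR peaks, 32.4 per Mb, and chromosome III 442, 32.1 per Mb. Density on the other autosomes ran from 22.9 per Mb on V to 27.9 on II. X held 20.96% of IDR peaks (95% interval 19.5 to 22.5%) and 19.5% of lower-ranked regions, a difference that did not pass the threshold (odds ratio 1.10, Fisher's exact test, p = 0.0665). It passed with either replicate list alone (Fisher's exact p = 0.0213 for replicate 2 and 0.00623 for replicate 1). Of X-linked IDR peaks, 49.3% were in a promoter, against 57.0 to 64.6% on each autosome. On autosomes, 63.3% of IDR summits (95% interval 61.2 to 65.3%) lay between 25% and 75% of the chromosome's length, against 58.5% of lower-ranked summits (odds ratio 1.22, Fisher's exact test, p = 2.91e-05).

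The AP-1 site TGASTCA, the element bound by FOS-JUN pairs, was more frequent at IDR peaks. It was within 50 bp of the summit in 93 of 2738 peaks (3.40%, 95% interval 2.75 to 4.15%) and in 1.498% of lower-ranked regions (odds ratio 2.31, Fisher's exact test, p = 1.76e-10). Windows 500 bp away from the same summits held it in 1.02%, and random positions in 0.818%. The share was 2.85% in the top-ranked regions of replicate 1 and 3.91% in those of replicate 2.

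Some other motifs were in more IDR windows than the AP-1 site. The patterns differ in length and in background share, so these shares do not rank enrichment. The GATA site TGATAA, bound by the intestinal GATA factors, was in 24.0% of IDR windows against 14.2% of lower-ranked ones (odds ratio 1.90, Fisher's exact test, adjusted p = 1.24e-34). The E-box CACGTG was in 6.98% against 2.16% (odds ratio 3.40, adjusted p = 1.24e-34), and the GAGA repeat GAGAGAGA in 6.28% against 1.91% (odds ratio 3.45, adjusted p = 5.08e-32), both by Fisher's exact test. Also higher were the EOR-1-like CTCTCTGC (1.72% against 0.426%), the Sp1/KLF site (1.497% against 0.601%), the CRE TGACGTCA (1.13% against 0.664%) and a C/EBP-like site (0.877% against 0.414%). In all, 8 of 14 motifs were higher at IDR peaks. The SL1 splice acceptor TTTTCAG (3.40% against 9.76%), the heat shock element, the Hox/PBC site and the TATA box were lower, while the SKN-1 and FOXO sites did not pass.

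GC content averaged 43.7% in IDR windows and 35.7% in lower-ranked ones. Against 3190 lower-ranked windows drawn to the same GC content, a comparison added after seeing the data, 7 motifs were higher. The AP-1 site (odds ratio 2.302, adjusted p = 5.66e-06), GATA, E-box, GAGA, EOR-1-like and C/EBP-like sites passed, and the SKN-1 site passed as well (5.77% against 3.86%, adjusted p = 0.00136), by Fisher's exact test. Some forms of the SKN-1 pattern WWTRTCAT hold the GATA site on the other strand. Such windows were not separated, so the SKN-1 pass is not shown to be distinct from the GATA site. The odds ratio of the EOR-1-like site fell from 4.09 to 1.67 (Fisher's exact test, adjusted p = 0.0423) and that of the GAGA repeat from 3.45 to 2.03, while that of the C/EBP-like site went from 2.13 to 3.52. The CRE (adjusted p = 0.661), Sp1/KLF site (0.942), heat shock element (0.0765), Hox/PBC site (0.942) and TATA box (0.942) no longer passed, all by the exact test. The CRE also missed the threshold with windows of 25 bp on each side (adjusted p = 0.244), the C/EBP-like site with 100 bp (0.0575) and the TATA box without replicate 2 (0.172), by the same exact test.

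**Figure D2:**
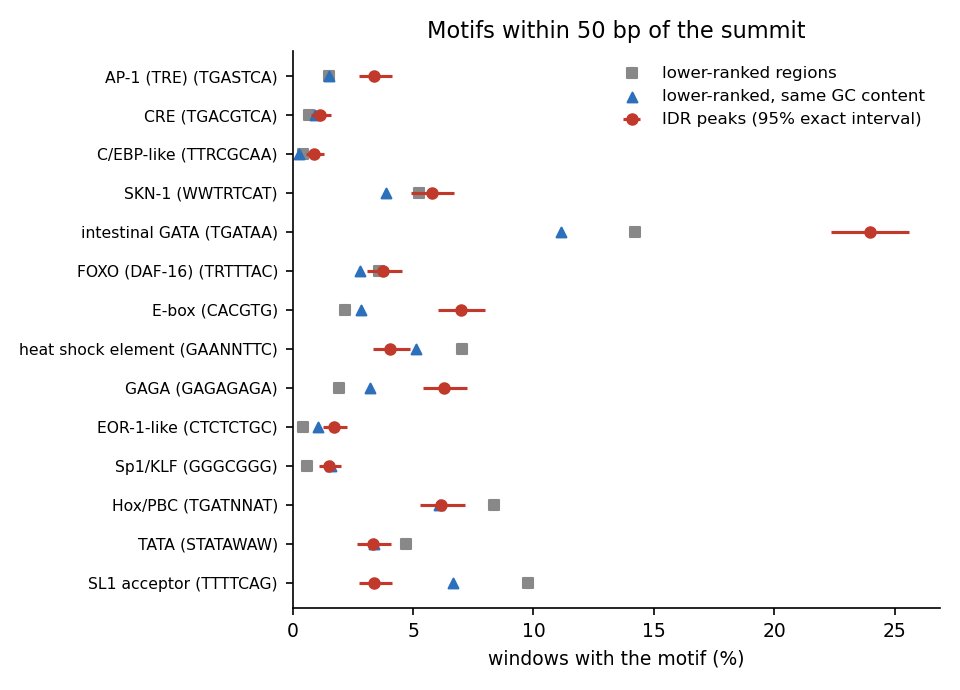
Percent of windows with each of the 14 motifs (x axis) at IDR peaks (red points, bars are exact 95% intervals), lower-ranked regions (grey squares) and lower-ranked regions of the same GC content (blue triangles). The GATA site reaches 24.0% of IDR windows, while the AP-1 site is at 3.40% against 1.498% in lower-ranked regions.

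An IDR summit lay in the promoter of 1902 protein-coding genes, 9.52% of all. Of the 27 gene lists, 10 held more bound genes than other coding genes did and 3 held fewer. Genes of the factor's own class stood out. Of 27 bZIP transcription factor genes, 18 were bound (66.7%, 95% interval 46.0 to 83.5%, odds ratio 19.2, adjusted p = 7.00e-12, Fisher's exact test). They included cebp-1, the unfolded-protein-response factor xbp-1 (signal value 137 pooled, 64.6 in replicate 1 and 69.7 in replicate 2), the pathogen-response gene zip-2 (110 pooled, 56.4 and 53.2), zip-5 (109 pooled, 31.1 and 78.0), the CREB gene crh-1 (109 pooled, 48.4 and 53.3) and zip-1 (81.8 pooled, 26.96 and 61.9).

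Genes of the AP-1 and JNK-type kinase list and of the p38 and innate immunity list were also bound more often. In the list of AP-1 and JNK-type kinase genes, 8 of 16 were bound (50%, 95% interval 24.7 to 75.3%, odds ratio 9.54, adjusted p = 0.000144, Fisher's exact test). These included the MAP kinase phosphatase gene vhp-1 (69.3 pooled, 29.1 and 43.1), the JNK-like kinase gene kgb-1 (56.5 pooled, 17.1 and 40.8), the MAP kinase kinase kinase genes mlk-1 (42.3 pooled, 23.8 and 13.5) and dlk-1 (38.5 pooled, 7.84 and 30.8), and the PAK-type kinase gene max-2 (34.9 pooled, 7.81 and 24.7). In the p38 and innate immunity list 11 of 24 were bound (45.8%, odds ratio 8.08, adjusted p = 1.97e-05, Fisher's exact test). They included zip-2, atf-7, a target of p38 signalling (78.2 pooled, 25.8 and 52.6), the TFEB-type gene hlh-30 (49.4 pooled, 7.68 and 44.2), the lysozyme genes lys-8 (48.5 pooled, 18.7 and 29.2) and lys-2 (37.2 pooled, 10.2 and 28.1), and spp-1 (47.7 pooled, 22.96 and 22.8). Members that were not bound included jnk-1, jkk-1, mek-1, mkk-4 and kgb-2 of the AP-1 and JNK-type list. In the p38 list they included tir-1, nsy-1, sek-1 and pmk-1. Both lists missed the threshold when only the 1369 strongest IDR peaks were used (adjusted p = 0.0944 and 0.0709, Fisher's exact test), with 3 and 4 bound members.

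The fos-1 gene, which encodes the FOS partner, had 4 IDR peaks within 10 kb. The strongest, at V 6000333 to 6000511, had its summit 3141 bp upstream of the gene, outside the promoter window (220 pooled, 100.2 in replicate 1 and 124 in replicate 2). A second at 6000466 to 6000855 lay next to it (64.9 pooled, 39.4 and 39.1). The peak that counted fos-1 as bound, at 6010653 to 6011042, was in the 5′ UTR of a shorter transcript inside the gene (55.1 pooled, 14.8 and 36.1). The last, at 6017623 to 6018012, was also the promoter peak of the proteasome gene rpt-2. No IDR peak lay within 10 kb of jun-1 itself.

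Ribosomal protein, translation factor, folding and respiratory chain genes were bound more often as well. Of 81 ribosomal protein genes, 50 were bound (61.7%, 95% interval 50.3 to 72.3%, odds ratio 15.7, adjusted p = 7.79e-30, Fisher's exact test). They were led by rpl-3, rpl-20 and rpl-15, followed by rpl-35 (253 pooled, 115.3 and 135), rps-1 (215 pooled, 99.6 and 114.9) and rpl-12 (203 pooled, 93.7 and 109). Of 40 translation factor genes 14 were bound (35%, odds ratio 5.15, adjusted p = 3.96e-05, Fisher's exact test), with the eIF5A gene iff-2 (224 pooled, 102 and 122), eef-1A.2, eef-1A.1, eef-2, eif-3.C and eef-1G at the top. Of 25 heat shock and folding genes 13 were bound (52%, odds ratio 10.4, adjusted p = 5.08e-07, Fisher's exact test). Among them were the chaperone genes hsp-90 (185 pooled, 74.6 and 110), hsp-1 (162 pooled, 48.0 and 114), hsp-3, which encodes a BiP of the endoplasmic reticulum (151 pooled, 65.6 and 85.6), hsp-60, hsp-110 and dnj-19. Members that were not bound included hsp-16.1, hsp-16.2, hsp-16.41, hsp-16.48, hsp-70, hsp-4 and hsf-1.

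Of 29 respiratory chain genes 14 were bound (48.3%, odds ratio 8.93, adjusted p = 5.08e-07, Fisher's exact test), including the cytochrome c oxidase genes cox-5A (189 pooled, 79.0 and 109), cox-5B and cox-6B, the ATP synthase gene atp-1, and mev-1 and cyc-1. The proteasome list had 11 of 31 bound (35.5%, adjusted p = 0.000238, Fisher's exact test), namely rpn-3, which shares its peak with hsp-110, rpt-2, rpn-9, pbs-1, rpn-11, rpn-2 and 5 more. The autophagy and lysosome list had 8 of 21 (38.1%, adjusted p = 0.00118, Fisher's exact test), with the Atg8-type genes lgg-2 (127 pooled, 56.0 and 71.4) and lgg-1 (121 pooled, 61.3 and 63.3), cpl-1, atg-3, hlh-30 and atg-9. The V-ATPase list had 6 of 21 (28.6%, adjusted p = 0.0258, Fisher's exact test), namely vha-12, vha-1, vha-8, vha-13, vha-15 and vha-17.

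Set only against coding genes with any pooled region in the promoter, of which 24.2% of those outside the list were bound, the autophagy (adjusted p = 0.0959), proteasome (0.0753), translation factor (0.0691) and V-ATPase (0.454) lists missed the threshold of Fisher's exact test. Their odds ratios were 2.78, 2.65, 2.31 and 1.71 in this setting, against 5.87, 5.25, 5.15 and 3.81 with all other coding genes. The ribosomal, respiratory chain, folding, bZIP, AP-1 and JNK-type, and p38 lists passed the threshold in this setting, with smaller odds ratios for ribosomal proteins (6.14), respiratory chain (5.50), folding (5.83), bZIP (11.3) and p38 genes (3.83). When each peak was assigned to the nearest 5′ end only, 26 of 81 ribosomal protein genes (32.1%, odds ratio 5.92) and 7 of 25 folding genes (28%, odds ratio 4.82) were bound, and both lists passed. Without the 100 strongest peaks, 9 folding genes were bound (odds ratio 5.59). The odds ratio of the bZIP list was 12.1 without replicate 1, and those of the AP-1 and JNK-type and p38 lists were 6.19 and 5.16 without replicate 2. The V-ATPase list also missed it without replicate 1 (adjusted p = 0.0817), with the nearest 5′ end only and on autosomes, each by Fisher's exact test.

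Chemoreceptor genes, cuticle collagens and homeobox genes were bound less often. Of 1276 chemoreceptor genes 15 were bound (1.18%, 95% interval 0.659 to 1.93%, odds ratio 0.106, adjusted p = 3.00e-36, Fisher's exact test), with srz-62 (200.7 pooled, 79.2 and 121) and srh-2 (160 pooled, 86.9 and 74.4) the strongest. Among coding genes with any pooled region in the promoter, the chemoreceptor odds ratio was nearer 1, at 0.334 (adjusted p = 5.40e-05, Fisher's exact test). Of 175 cuticle collagen genes 6 were bound (3.43%, odds ratio 0.335, adjusted p = 0.00975, Fisher's exact test), among them col-38 and col-85. Of 83 homeobox genes 2, ceh-38 and ceh-39, were bound (2.41%, adjusted p = 0.0472, Fisher's exact test). The homeobox call did not pass in 9 of 10 alternatives and was kept only with matched gene sets.

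Lists of tissue markers and developmental pathways did not pass. Of 24 intestine markers 5 were bound (20.8%, adjusted p = 0.129, Fisher's exact test), including the GATA factor gene elt-2 (129 pooled, 50.2 and 79.3), cpr-1, fat-6 and act-5. With replicate 2 alone 7 were bound and the list passed (exact test, adjusted p = 0.0134). Among insulin signalling genes, 4 of 18 were bound, namely ftt-2, akt-2, par-5 and daf-16 (22.2%, adjusted p = 0.144, Fisher's exact test), and the list passed with replicate 1 alone (5 bound, adjusted p = 0.0337) and with promoters from 2000 bp upstream (6 bound, adjusted p = 0.0357). Nuclear hormone receptor genes had 36 of 274 bound (13.1%, adjusted p = 0.0928, Fisher's exact test), led by nhr-291, nhr-50, nhr-68 and nhr-47, and passed with replicate 1 alone (adjusted p = 0.00873) and with the nearest 5′ end only (0.00882).

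No list of markers of another tissue passed either. Bound were 3 of 26 neuron markers (snb-1, syd-2 and unc-119), 2 of 22 body wall muscle markers (act-4 and unc-112), 2 of 23 epidermis and seam markers (vab-10 and ajm-1), 1 of 30 germline markers (cgh-1) and 0 of 16 pharynx markers (95% interval 0 to 20.6%). Also not called were histones with 8 of 50, led by his-37 (213 pooled, 88.7 and 126) and his-24, oxidative stress with 1 of 28 (wdr-23), and developmental timing with 2 of 19 (lin-28 and lin-14). Vulval and Wnt, Notch and EGF signalling had 2 of 29 (sem-5 and egl-17), anchor cell invasion and spermatheca 2 of 16 (unc-40 and lfe-2), and SKP1-related ligase parts 2 of 23 (lin-23 and skr-19). Lists of this size leave wide intervals, and some counts changed with the replicate used. Without replicate 1, 4 oxidative stress genes and 1 pharynx marker were bound, and without replicate 2, 4 germline markers, 4 developmental timing genes, 2 oxidative stress genes, 1 vulval and Wnt, Notch and EGF gene and 1 epidermis marker, with no call in any of these lists.

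**Figure D3:**
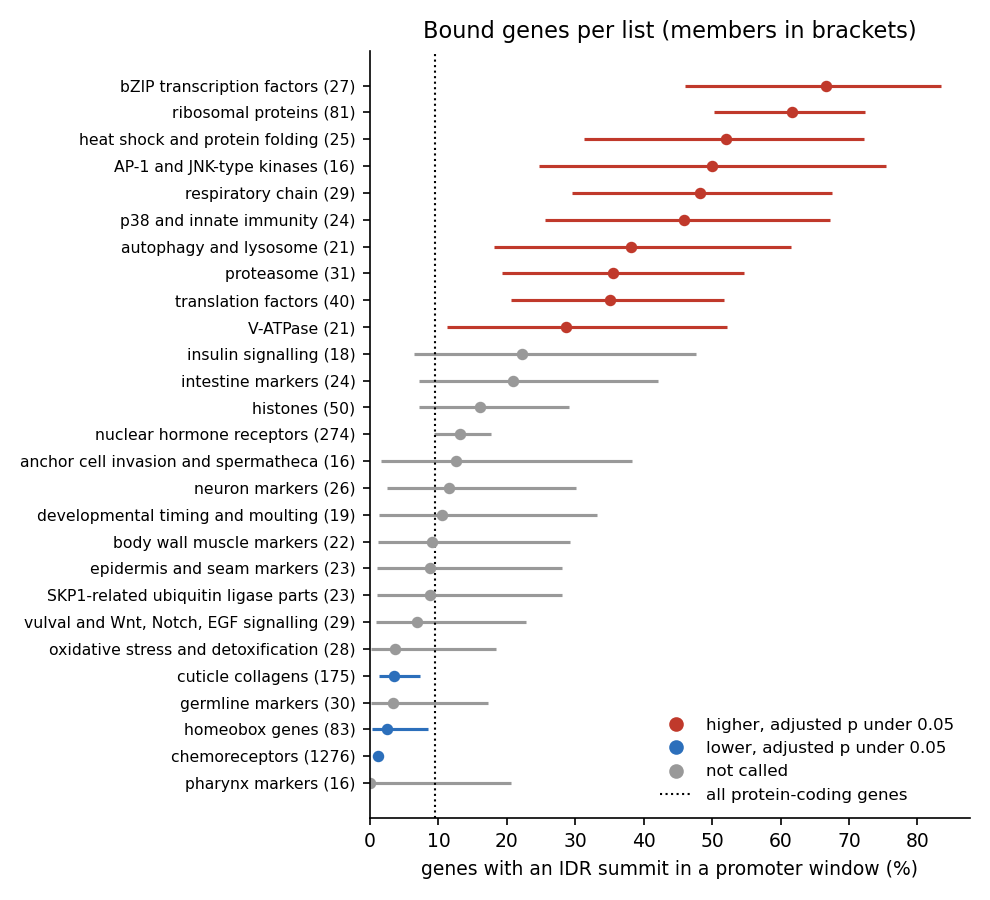
Percent of the genes of each of the 27 lists that have an IDR summit in a promoter window (x axis, points with exact 95% intervals, members in brackets), coloured by the call against all other coding genes, with 9.52% of all coding genes as a dotted line. The bZIP list is highest at 66.7% and ribosomal proteins follow at 61.7%, while chemoreceptors are at 1.18%.

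Transfer RNA and small nucleolar RNA genes lay near IDR peaks more often than protein-coding genes. An IDR summit was inside or within 250 bp of 109 of 612 tRNA genes (17.8%, 95% interval 14.9 to 21.1%) and 64 of 346 snoRNA genes (18.5%, 95% interval 14.5 to 22.997%), against 8.24% of protein-coding genes (odds ratios 2.41 and 2.53, adjusted p = 3.50e-13 and 4.52e-09, Fisher's exact test). Pseudogenes (1.41%, adjusted p = 1.68e-40), piRNA genes (0.378% of 15363), miRNA genes (10 of 261, 3.83%, adjusted p = 0.0140) and other ncRNA genes (6.83%, adjusted p = 0.000152) were lower, by Fisher's exact test. Gene length was not matched in these comparisons, and a longer gene offers more sequence in which a summit can lie. Lower shares in classes of short genes may therefore reflect length and are not read as avoidance. The snoRNA call was lost when the summit had to be inside the gene (4.34%, exact test, adjusted p = 0.497), and so was that of other ncRNA (adjusted p = 0.167). With the 1369 strongest IDR peaks, miRNA (adjusted p = 0.626) and other ncRNA genes (0.861) missed the threshold, while with replicate 2 alone lincRNA genes passed it (13.4%, adjusted p = 0.0187), all by the exact test.

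The transgene adds copies of the tagged locus, so the regions around jun-1 and around unc-119 were counted. No list held a region over jun-1 (II 9113157 to 9132231). The space without regions ran from 9101417 to 9138289 in the pooled list, 36.9 kb, from 9101436 to 9139095 in replicate 1 and from 9099375 to 9138314 in replicate 2. Of the 222 protein-coding genes at least as long, 15 overlapped no region of the pooled list, 4 none of replicate 1 and 5 none of replicate 2, and jun-1 was the 1 gene with none in all 3 lists (0.450%, 95% interval 0.0114 to 2.48%). A 40 kb window centred on jun-1 held 3 pooled regions against a median of 8, and 18.4% of such windows centred on coding genes held as few (11.4% without replicate 1 and 3.28% without replicate 2). The window around unc-119 held 6, and 40.9% of windows held as few (21.6% without replicate 1 and 43.9% without replicate 2). The unc-119 gene had 1 IDR peak, at III 10905273 to 10905662 in an intron, whose signal value of 31.8 (11.7 in replicate 1 and 19.4 in replicate 2) was close to the lowest in the IDR list.

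**Figure D4:**
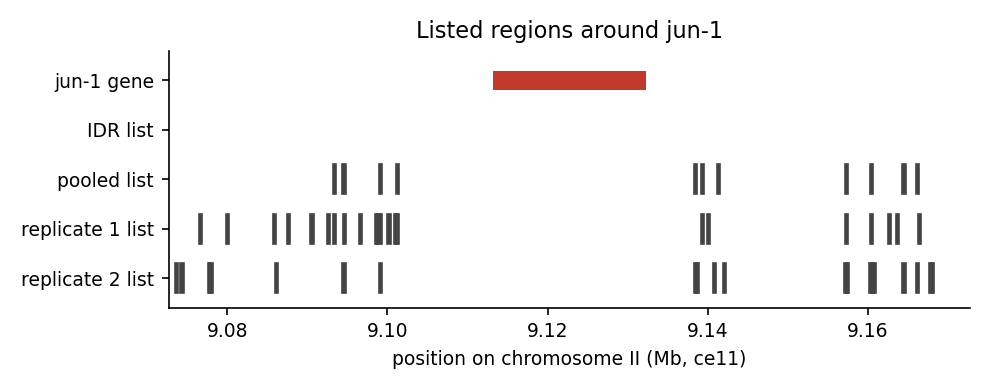
Listed regions (dark bars, drawn to scale) within 50 kb of the middle of jun-1 on chromosome II (x axis, position in Mb on ce11) in the IDR, pooled and replicate lists, with the gene in red. The gene lies inside a span of 36.9 kb without a region in the pooled list, and both replicate lists are also empty there.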

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

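Across 12 results and 71 alternatives, 59 left a tested result on its side of the threshold, a value within its spread or a count within 1.5 times of that reported, 4 brought a result past the threshold, 8 moved a value and 0 reversed one. Alternatives on GC content, autosomes, the 100 strongest peaks, matched gene sets and random draws were chosen after seeing the data. Promoter share, chromosome centre share, AP-1 motif share and replicate overlap passed their tests in each alternative run for them. The X share, not past the threshold as reported, passed it against genome length (20.96%, against 17.7% expected), for the 100 strongest peaks (36%), and with each replicate alone (20.8 to 21.7%). The IDR count fell to 1369 by construction when only the stronger peaks were kept. Matching summits within 50 bp raised rho to 0.583. A count within 1.5 times can hide lost calls: called gene lists fell to 10 and noncoding classes from 6 to 4 with the stronger peaks, and the homeobox call was lost in 9 of 10 alternatives. Called gene lists fell from 13 to 8 when the background was genes with any pooled region. This background had fewer genes, and the odds ratios of the higher lists that were lost were also smaller. For jun-1, the share of windows with as few regions was 9.77% with 20 kb windows and 3.28 to 11.4% with single replicates, and for unc-119 71.1% and 21.6 to 43.9%. Except where construction is named, the cause was not tested. No paired analysis was possible because the series has 1 group. Read depth is unknown, so the share of sites missed by the lists cannot be given.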

Other observations

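The tests of X peaks ranked 26 to 100, of X copy number, and of the length, genes and ends that concern the space over jun-1 were chosen only after the result they concern was seen, as was the scan of 7-base words. In that scan, 6784 words were compared between windows of 50 bp around IDR summits and lower-ranked windows of the same GC content. The 3 words with the lowest p overlap the GATA site, led by CTTATCA in 12.7% of IDR windows against 4.33% (odds ratio 3.23, adjusted p = 1.29e-28, Fisher's exact test). Next came purine-rich words such as AGAGAAA (14.97% against 8.09%) and AGAGACG (9.64% against 4.29%), then ACGCAGA (9.86% against 4.51%). CTGGCGC (3.73% against 0.846%), CACGTGA, which holds the E-box (4.31% against 1.25%), and TGACGCA (2.99% against 0.721%) were rarer, with odds ratios of 4.53, 3.55 and 4.25. The longest space without a pooled region was 226 kb on chromosome V, from 2339309 to 2565393, where 96.1% of 31-base words occur more than once in the genome, against 8.73% genome-wide.

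Of the 25 strongest peaks 17 were on X, most of them outside promoters. The pattern was noticed in these 25 and did not extend clearly below them: X held 19 of the 75 peaks ranked 26 to 100 (25.3%) against 20.4% of the other 2638 (Fisher's exact test, p = 0.310). A match to at least 10 of the 12 bases of MEX, the sequence TCGCGCAGGGAG known from sites that recruit the dosage compensation complex to X, lay within 100 bp of the summit in 38.9% of the 36 X peaks among the 100 strongest (95% interval 23.1 to 56.5%), against 1 of 64 autosomal ones (Fisher's exact test, p = 9.81e-07). This difference among the 100 strongest rests mainly on the 25 strongest, where 12 of the 17 X peaks had a match. In ranks 26 to 100 matches were 2 of 19 on X against 1 of 56 on autosomes, too few to decide (Fisher's exact test, p = 0.156). Over all IDR peaks, the 25 strongest included, matches were 26 of 574 on X against 18 of 2164 on autosomes (Fisher's exact test, p = 3.03e-08). Between the 100 strongest and rank 500, matches were 2 of 86 on X (2.33%) against 5 of 314 on autosomes (1.59%). Among the weaker IDR peaks, those past rank 500, matches were rare but more frequent on X (10 of 452, 2.21%, against 12 of 1786, 0.672%). Lower-ranked regions had 0.641% on X against 0.352%. The differences past the 100 strongest peaks and in lower-ranked regions were not tested. Repeated sequence is argued against, since the median share of 31-base words occurring more than once was 0% at the 36 X peaks. A difference in copy number or depth of the whole chromosome would act on X peaks of every rank. It is argued against as the only source of the pattern. X held 17 of the 25 strongest peaks, but 25.3% of ranks 26 to 100 and 20.4% of the other 2638. The median signal value of X-linked IDR peaks was 48.5, within the range of 45.7 to 49.1 on the autosomes. Whether such a difference adds to the X share of weaker regions is left undecided. The X share of the IDR peaks below the 100 strongest was 0.934 percentage points above that of lower-ranked regions. A difference of the whole chromosome could raise both of these shares alike, so this comparison cannot decide whether it adds to them. X made up 17.7% of the genome and held 19.5% of lower-ranked regions. A hypothesis that remains is that the tagged factor, or chromatin recovered in this assay whatever the factor, may be found at some recruitment sites of the dosage compensation complex; lists for other factors and for controls were not analysed here, so these cannot be separated.

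Bound genes were concentrated in 10 of the 27 lists, with the highest shares among bZIP factors, ribosomal proteins and folding genes. Length of promoter windows and chromosome position are argued against, since 13 of 13 called lists passed with gene sets matched on both (10000 random draws each). An origin in promoters that gather reads at any threshold stays open: of the 161 genes of the 10 higher lists with no IDR peak, 68.3% had a lower-ranked region in the promoter (95% interval 60.5 to 75.4%), against 32.5% of 17910 other genes without one (odds ratio 4.47, Fisher's exact test, p = 2.99e-20). The AP-1 site TGASTCA was found at 4 of 144 listed peaks (2.78%, 95% interval 0.762 to 6.96%), so most of them lacked it. Of 1440 other promoter peaks 3.33% held it (Fisher's exact test, p = 1). The counts are too few to tell whether the listed peaks differ from these. Variants of the site were not compared between the 2 sets. As the series has 1 group, no explanation from a difference between groups was tested.

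No region was listed over jun-1 in the pooled or either replicate list. Repeated sequence is argued against, since 5.36% of the 31-base words in the space occur more than once, below the 8.73% of the genome. Ordinary spacing was tested in 3 forms, each written after the space was seen, and they disagree. Of the spaces in the pooled list 0.951% were as long, a form weighted against ordinary spacing, because this space was picked for holding a long gene. Of the 222 protein-coding genes at least as long as jun-1, which was named in advance as the tagged gene, jun-1 was the 1 gene with no region in all 3 lists (0.450%, 95% interval 0.0114 to 2.48%). In the pooled list alone 15 had none (6.76%, 95% interval 3.83 to 10.9%). The first 2 forms go against ordinary spacing and the third does not, nor does the planned measure, the share of 40 kb windows with as few regions (18.4% in the pooled list and 11.4% without replicate 1, but 3.28% without replicate 2). Of the 179 pooled spaces as long, 2 had both ends within 3 kb in both replicate lists, and 1 of these, that over jun-1, was no more repeated than the genome. The ends over jun-1 differed by at most 2.06 kb, but the 3 kb limit was set after they were seen. Extra copies of the tagged locus, or a filter acting on them, may have set the span, and spacing and the transgene cannot be told apart here: the forms disagree, none was fixed beforehand, and control data were not analysed here.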
